A study of Mus musculus with 9 samples.

How the data were processed

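The series measured RNA from the hippocampus of male SAMP10 mice, an inbred senescence-accelerated strain that shows early brain ageing. Per the labels' protocols, mice ate a standard diet, alone or with 3.0% of an extract of yellow or green soybean, from 1 to 12 months of age, in 5 diet groups of 12 mice with 6 mice to a cage. The 9 arrays analysed here cover 3 of those diets, with 3 arrays each for the control, yellow soybean and green soybean diets. The groups were taken from the sample labels. The sample titles carry the name SMP30 where the strain label says SAMP10, and the strain label was followed. No label says whether an array held RNA from a single mouse or a pool, or that arrays came from separate mice, so the p-values measure the spread between these samples, which could be technical in part. The labels also name no cage for any array, so effects of cage and of diet cannot be told apart here.

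Per the labels' protocols, total RNA was isolated with RNeasy columns and turned into biotinylated cRNA for a 1-colour Affymetrix array. The authors deposited 1 normalized score per probe set and array, on a z-type scale made by the SuperNORM data service per the labels. A deposited table also gives 1 p-value per probe set, whose test and comparison are not given in the sources used here. It also holds 9 value columns that match no label and were not used. A further deposited table gives the normalization parameters of 9 arrays under names that match no label. From those parameters only medians and ranges were taken. The scale parameter had a median of 0.705 (range 0.655 to 0.720). If the underlying logarithm has base 10, which was inferred from plausible intensities and is not stated, 1 unit of the score is about 2.34 on the log2 scale and 0.1 unit is about 1.18-fold. Differences are given in score units for this reason.

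The deposited table holds 34760 probe sets, of which 21640 carried 1 gene symbol in the platform annotation, 1321 carried several and 11799 had none. Gene names follow that annotation, and whether a probe set detects the named gene's own transcript or a related sequence was not tested. The 6573 probe sets numbered below the first annotated one were treated as control-type and left out. Of the other 28187, 6228 held an exact 0 on at least 1 array, 2688 of them on all arrays. An exact 0 was read as no value, because probe sets with high scores on some arrays held it on others. The remaining 21959 probe sets had a score on all 9 arrays and were tested. Exact zeros made up between 14.2% and 17.7% of an array. For arrays, the number of arrays limits the precision, and the median standard error of a difference between groups was 0.0632 units.

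Among the tested probe sets, 1345 had a control mean of 0 within 1e-06, so the authors had centred their scores on the controls. These were the probe sets with a deposited p-value below 0.005, the largest among them being 0.00497 and the smallest among the others 0.00501. The mean score of a centred probe set is not a signal level. The design fixed before the data were examined kept probe sets with a mean score at or above the median and modelled the spread with an intensity trend. On these scores that filter keeps 10980 probe sets and drops 1302 of the 1345 centred ones, so it removes probe sets by the authors' own p-value. The design was therefore not used as written. A first replacement, which dropped the dimmer probe sets and kept all centred ones, favoured the centred probe sets in turn. The setting reported uses all 21959 complete probe sets with no intensity trend. It was chosen after the results of all 3 settings had been seen. The choice does not alter the number of probe sets called, but it does alter which gene lists are called, and the values of the design as written stand beside those lists.

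Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on the deposited scores, with 1 model over the 9 arrays, no covariates, and 2-sided tests. The comparisons were green versus control, yellow versus control, green versus yellow, and a moderated F-test over the 3 diets. Benjamini-Hochberg adjustment ran over all probe sets tested, with calls at an adjusted p below 0.05. Gene lists were tested with camera in limma, 1 probe set per gene (the highest mean score), a preset correlation between genes of 0.01 and adjustment over the lists. For the 120 genes with both a centred and another probe set, the mean score is not a level for both. The choice between their probe sets was therefore not made by signal. Correlations estimated from the data and limma's fry served as alternatives. The 27 lists were fixed before the data were examined. They comprise 13 pathway lists and 14 marker lists of cell types and neighbouring structures, and 386 of their 438 genes lay on a tested probe set. The rule for named genes, also fixed in advance, takes genes past the threshold, otherwise up to 5 genes per direction with the smallest p, and from each list the members with the smallest p. Probe sets with several or no symbols and genes named only by a clone or locus were not named, and 1 gene that the rule takes for green versus yellow is not reported here.

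The limma steps were tested on simulated data for green versus control over 21959 probe sets. Calls recovered 0% of probe sets shifted by 0.1 unit, 6% at 0.2, 68% at 0.4 and 96% at 0.8, with 2 false calls among the unshifted ones. In a simulation over 16429 genes, a list shifted by 0.15 unit was called by camera and 0 of the other 26 lists were. Its genes were drawn independently, so it does not show how often camera calls lists whose genes vary together. The estimated correlation and fry were not run on simulated data, so a call that ends under them does not show that a difference is absent. In the real data the estimated correlation was 0.659 for activity-regulated genes. The correlation between the effects of both extracts was set beside 100 simulated unchanged groups sharing the same controls. Alternatives were quantile normalization, alignment of array medians, only the brightest probe sets, the intensity trend, array weights, the 6 arrays of a comparison alone, leaving out each array, a replicate block, the mean of a gene's probe sets, and the handling of the centred probe sets. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.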

Results

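Hippocampal RNA of SAMP10 mice was compared after long-term feeding of a control diet, a diet with yellow soybean extract or a diet with green soybean extract, on 9 arrays with 3 arrays per diet. The title of the series names memory-related decline and build-up of amyloid beta as the traits of ageing that the green extract was studied for. Expression is given as the authors' normalized score, and every difference is in units of that score. Arrays correlated closely across the 20614 uncentred probe sets tested, with a mean correlation of each array with the other 8 between 0.977 and 0.981 for 8 arrays. Green soybean replicate 3 stood apart, with a mean correlation of 0.958 and a spread of its difference from the other arrays of 0.160, against 0.0783 to 0.101 for the others. The median of the 3676 complete, uncentred control-type probe sets lay between 0.188 and 0.227 on the 9 arrays.

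**Figure D1:**
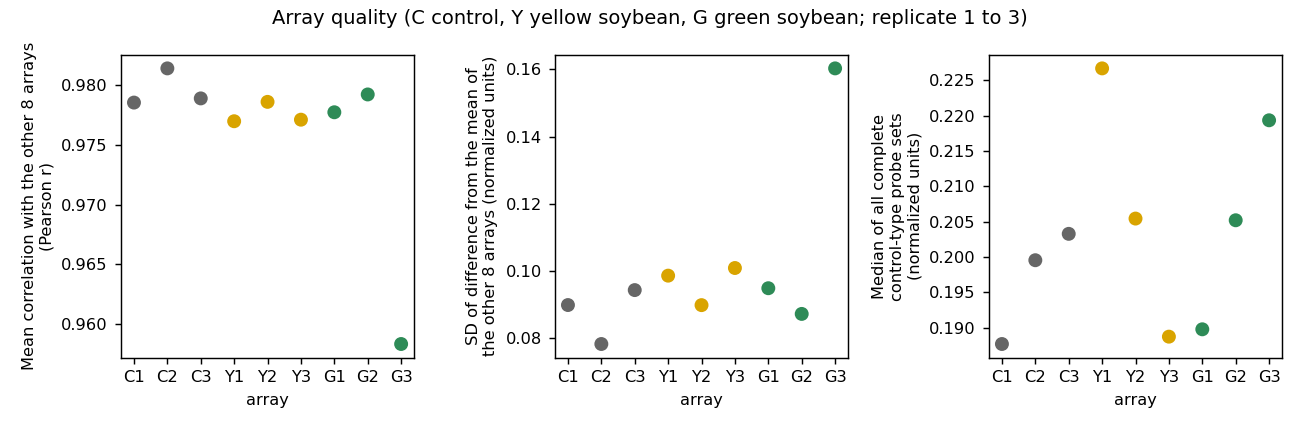
Each point is 1 array, grouped by diet (C control, Y yellow soybean, G green soybean), and the panels plot the mean Pearson correlation with the other 8 arrays, the SD of the difference from their mean in normalized units, and the median of 3676 control-type probe sets in normalized units. Green soybean replicate 3 lies at 0.958 in the first panel and 0.160 in the second, and the third panel spans 0.188 to 0.227.

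The comparison of green soybean with control asks which hippocampal transcripts differ after feeding of the green extract. Among genes that bind or clear amyloid beta, Ptgds, the prostaglandin D2 synthase that leptomeningeal cells secrete into cerebrospinal fluid, averaged 0.569 ± 0.146 (SD, n = 3) with green soybean and 0 ± 0.109 in controls, and the 3 green arrays lay above the 3 control arrays. Aplp1, a relative of the amyloid precursor protein, averaged -0.817 ± 0.181 against 0 ± 0.628, with control replicate 2 at -0.713 inside the green range. App itself, the amyloid precursor gene, averaged -0.0290 ± 0.0549 against a control mean of 0 ± 0.0939. None of these passed the test, with limma adjusted p = 0.438 for Ptgds and 0.471 for Aplp1. Of the 21 measured genes of amyloid precursor processing, 10 were higher, 11 lower and 0 passed, and of the 18 measured genes of amyloid beta binding and clearance, 9 were higher, 9 lower and 0 passed.

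Across all probe sets, limma called 0 higher and 0 lower with green soybean than in controls, the smallest adjusted p being 0.315. At an unadjusted p below 0.05 there were 2134 probe sets, 1827 higher and 307 lower, where 1098 would arise by chance. This excess was not seen among brighter probe sets, with 557 of 10980 under the design as written (549 by chance) and 155 of the 5490 brightest (274 by chance), and was smaller, 855 of 11652 (583 by chance), with only the dimmer uncentred ones left out. The share of the 2134 that were higher was 85.6% on the deposited scores, and became 55.5% with array medians aligned and 47.4% after quantile normalization. Both remove a general shift between arrays, which moves this share, but they need not make it even. With medians aligned it was 64.0% for green versus yellow. Among the 155 such probe sets for green versus control of the brightest ones tested alone, with no rescaling, the share was 55.5%. In 2898 probe sets the 3 green arrays lay above the 3 controls and in 586 below, together 15.9%, where chance gives 10%. The self-test recovered 6% of probe sets shifted by 0.2 unit, so differences of that size were rarely detectable with these arrays.

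The higher genes with the smallest p values included Rpl7a, a protein of the large ribosomal subunit, with a difference of 0.440 ± 0.0701 (SE), and Nfu1, a mitochondrial iron-sulfur cluster protein, with 0.737 ± 0.140. Fggy, a carbohydrate kinase, differed by 0.467, Ccn4, a matricellular Wnt target, by 0.302, and Cd300c2, a myeloid surface receptor, by 0.280. Among the lower genes were Sumo2, a ubiquitin-like modifier, at -0.306, Ano3, a transmembrane scramblase-family protein, at -0.284, Dnajc13, an endosomal co-chaperone, at -0.251, Apold1, an endothelial early response gene, at -0.235, and Cdh11, a mesenchymal cadherin, at -0.184. None passed, with limma adjusted p values from 0.315 to 0.431. The median of the mean scores of the probe sets tested was 0.128. In controls Rpl7a, Nfu1, Ccn4, Cd300c2 and Dnajc13 lay below it, at -0.426, -0.285, -0.565, -0.300 and -0.240, so these probe sets were dim. Whether these dim probe sets detect the transcripts of the genes they are named for was not tested. Sumo2, Cdh11 and Apold1 lay above it, at 1.44, 1.58 and 0.331, while Fggy and Ano3 were centred and show no level. Nfu1 was called without green soybean replicate 3, whose score of 0.0169 lay far below the other green arrays, with a difference of 0.954 and limma adjusted p = 6.58e-04.

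**Figure D2:**
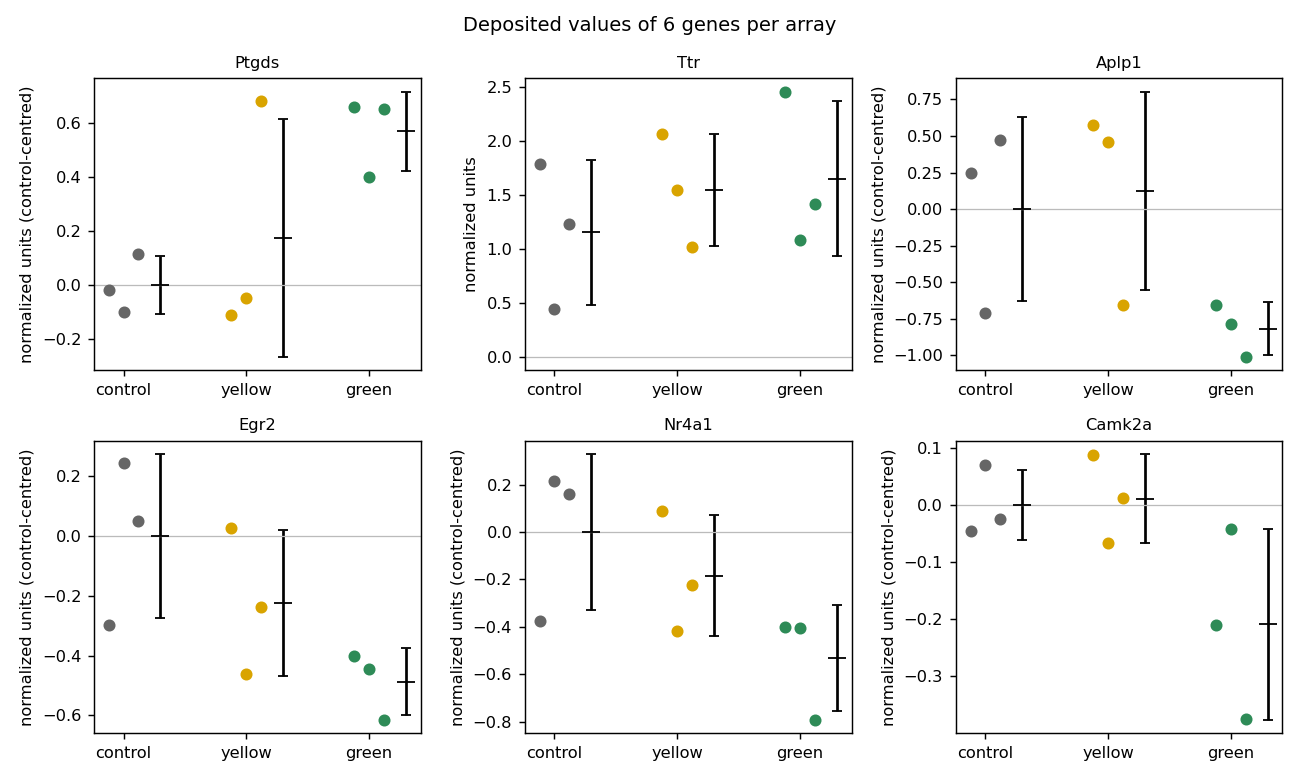
Points are the deposited scores of single arrays in normalized units for 6 genes, by diet, with the group mean and SD drawn beside them. The 3 green arrays lie above the control arrays for Ptgds, at 0.401 to 0.657, and below them for Egr2 and Nr4a1. For Nr4a1 the gap is narrow, with control replicate 1 at -0.376 and green soybean replicate 1 at -0.399. Aplp1 has control replicate 2 at -0.713 and yellow soybean replicate 3 at -0.653.

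Of the 27 gene lists, 4 were called for green soybean against control by camera at its preset correlation, relative to all other genes. The median difference over all probe sets tested was 0.0296 for green versus control, 0.0140 for yellow versus control and 0.0147 for green versus yellow. More probe sets were therefore higher than lower in each comparison, and counts of higher list members stand against that background. Activity-regulated genes, the immediate early genes that neurons induce on firing, were lower, with 14 of 17 members below control and limma camera adjusted p = 3.30e-08, and adjusted p = 0.793 with an estimated correlation. Egr2 and Nr4a1, both inducible transcription factors, differed by -0.486 and -0.532, Dusp1, a phosphatase of MAP kinases, by -0.394 and Junb, an AP-1 subunit, by -0.246. Adjusted over the list alone, 4 members passed, and over all probe sets 0 did. The mean of the list per array averaged 0.0764 ± 0.172 (SD, n = 3) in controls and -0.0998 ± 0.120 with green soybean (exact permutation p = 0.30, where 0.1 is the smallest p possible), because control replicate 1 lay at -0.120.

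Synaptic transmission genes were also lower relative to other genes, in 14 of 19 members (limma camera adjusted p = 0.00332, and adjusted p = 0.793 with an estimated correlation), among them Camk2a, a kinase of synaptic plasticity, at -0.209, and Grin2b, an NMDA receptor subunit, at -0.163. Without green soybean replicate 3, Camk2a stood at -0.126 and Grin2b at -0.0513. Glucocorticoid response genes were lower in 8 of 13 members (limma camera adjusted p = 0.0180, and adjusted p = 0.793 with an estimated correlation), led by Pdk4, an inhibitor of pyruvate dehydrogenase, at -0.289 and Errfi1, a feedback inhibitor of EGF receptor signalling, at -0.240. Pdk4 stood at -0.179 without control replicate 3. Markers of the leptomeninges, the membranes that cover the brain, were higher in 14 of 16 members (limma camera adjusted p = 0.00324, and adjusted p = 0.793 with an estimated correlation). They included Fmod, an extracellular matrix proteoglycan, at 0.314 and Slc13a4, a sulfate transporter, at 0.297. Adjusted over the list alone, 0 members of these 3 lists passed. For list means per array, exact permutation p was 0.30 for synaptic transmission, 0.50 for glucocorticoid response and 0.20 for the leptomeninges. Green and control arrays overlapped in each, and in glucocorticoid response control replicate 2, at -0.0342, lay below all 3 green arrays. Under the design as written, the adjusted p was 0.0157 for the leptomeninges, 0.30 for activity-regulated and synaptic genes and 0.748 for glucocorticoid response. The leptomeninges call there rested on 4 measured members and ended with an estimated correlation (camera adjusted p = 0.88). With the centred probe sets left out the values were 0.295, 0.391, 0.173 and 0.653 for leptomeninges, activity-regulated, synaptic and glucocorticoid lists, and without green soybean replicate 1 they were 0.101 for leptomeninges and glucocorticoid response and 0.0605 for synaptic transmission. The glucocorticoid call also ended without control replicate 3 (0.299) or green soybean replicate 2 (0.0517), and the synaptic call with only the dimmer uncentred probe sets left out (0.0503).

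The other 23 lists were not called for green soybean in the reported setting. Their counts of higher members stand against the positive median difference over all probe sets, 0.0296. Choroid plexus markers were higher in 14 of 17 members (camera adjusted p = 0.145), GABAergic interneuron markers in 11 of 13 (0.387), oxidative phosphorylation genes in 17 of 21 (0.522), antioxidant defence genes in 16 of 21 (0.522) and microglia markers in 8 of 11 (0.438). Among members of these lists, Gpx1, a glutathione peroxidase, differed by 0.229. Circadian clock and cholesterol synthesis genes both had a camera adjusted p of 0.0543. Amyloid precursor processing and heat shock genes stood at 0.145, amyloid beta binding and clearance at 0.567, inflammation and complement at 0.872, interferon response at 0.489 and oestrogen receptors and targets at 0.522. Heat shock genes were the only list called, as lower, with the centred probe sets left out. They were also called with a gene's probe sets averaged and without control replicate 1. Circadian, cholesterol synthesis and choroid plexus lists were each called in some alternatives too. Oligodendrocyte markers were called without control replicate 1, and dentate gyrus granule cell markers without control replicate 3. Of the markers, camera gave 0.925 for ependyma, 0.533 for striatum, 0.748 for thalamus and habenula, 0.872 for neocortex, 0.165 for dentate gyrus granule cells, 0.145 for cornu ammonis pyramidal cells, 0.136 for astrocytes, 0.427 for oligodendrocytes, 0.855 for endothelium and pericytes and 0.438 for blood. The test direction opposed a positive median and mean for inflammation and complement, ependyma, thalamus and habenula, and endothelium and pericytes. Camera compares a list with all other genes, not with 0. The heat shock and circadian lists had a positive median with a negative mean, and amyloid beta binding and clearance a negative median with a positive mean.

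**Figure D3:**
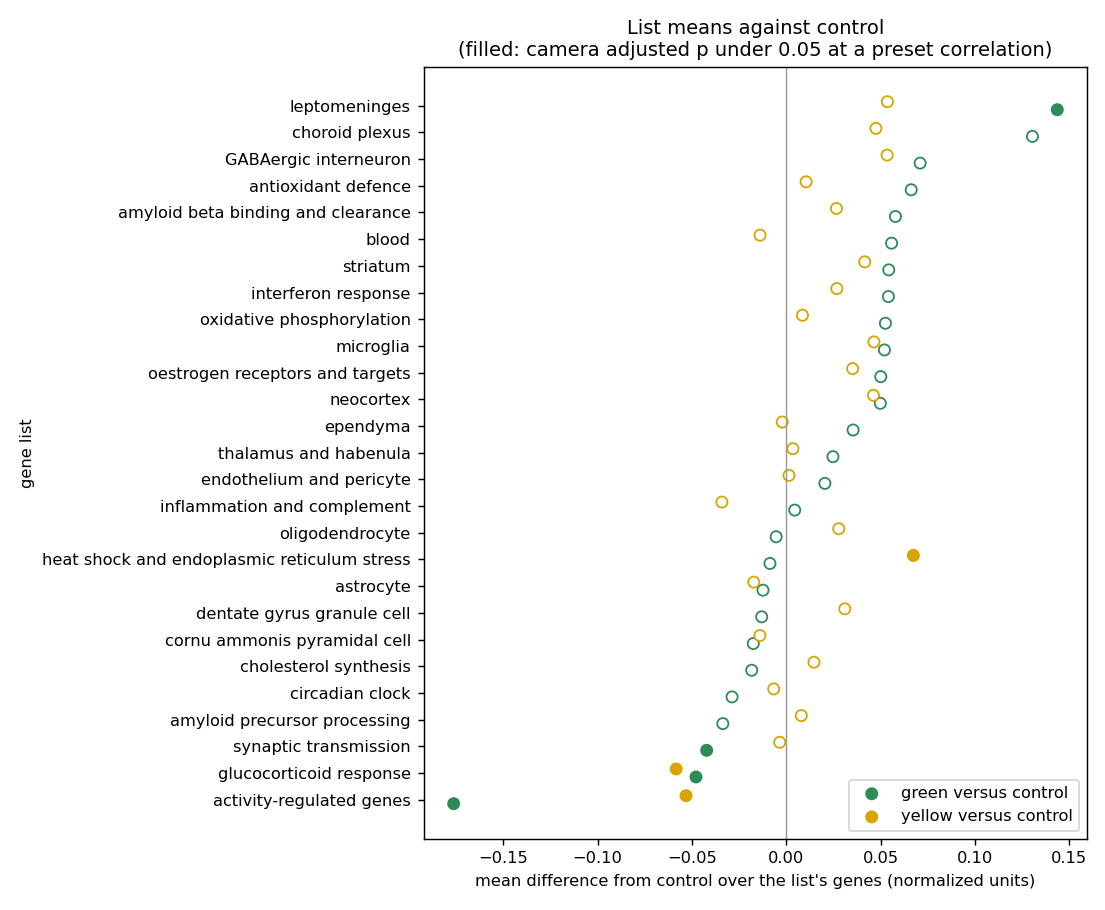
The horizontal axis gives the mean difference from control over the genes of each list, in normalized units, for green and yellow soybean, and filled points mark lists with a camera adjusted p below 0.05 at the preset correlation. Activity-regulated genes and leptomeninges markers lie at the ends of the green series, at -0.176 and 0.144.

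The comparison of yellow soybean with control asks the same of the yellow extract. Me1, the cytosolic malic enzyme that supplies NADPH, averaged 0.724 ± 0.0136 (SD, n = 3) with yellow soybean and 0.409 ± 0.0874 in controls, and Acaa1b, a peroxisomal thiolase, differed by 0.333. Ftl1, the ferritin light chain, differed by 0.380, Tmed10, a cargo receptor of the secretory pathway, by 0.356 and Cetn3, a centrosomal centrin, by 0.234. Lower genes included Erap1, an aminopeptidase that trims antigenic peptides, at -0.251, Spata21 at -0.236, Nudt1, which removes oxidized nucleotides, at -0.217, Olfr414, an olfactory receptor, at -0.204 and Pnma3 at -0.195. None passed, with limma adjusted p = 1.00 for each. In controls Acaa1b, Ftl1 and each of the lower genes averaged between -0.559 and -0.130, below the median of 0.128 over the probe sets tested. Me1, Cetn3 and Tmed10 lay above it, at 0.409 to 0.571. In the amyloid lists, 11 of 21 precursor processing genes and 10 of 18 binding and clearance genes were higher and 0 passed. Ptgds differed by 0.173, by -0.0797 without yellow soybean replicate 3, by 0.315 without yellow soybean replicate 1 and by 0.284 without yellow soybean replicate 2.

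Over all probe sets limma called 0 for yellow soybean, with 667 at an unadjusted p below 0.05, 463 higher and 204 lower, against 1098 by chance. The model shares 1 spread over the 9 arrays, and the count depends on which arrays set it. It was 983 without green soybean replicate 3 and 975 with only the 6 arrays compared, where the smallest limma adjusted p was 0.193. Leaving out yellow soybean replicate 2 gave 1059, array weights 1091, and the design as written 174 of 10980 (549 by chance). The higher share of 69.4% became 44.7% with array medians aligned and 53.1% after quantile normalization, and was 74.3% among the brightest probe sets without rescaling. The yellow arrays lay wholly above the controls in 1460 probe sets and below in 583, together 9.30%, where chance gives 10%.

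Glucocorticoid response genes were lower with yellow soybean in 8 of 13 members (limma camera adjusted p = 0.00383, and adjusted p = 0.916 with an estimated correlation), with Ddit4, a stress-induced inhibitor of mTOR, at -0.154 and Sgk1, a serum- and glucocorticoid-induced kinase, at -0.160, or -0.0716 without control replicate 3. Activity-regulated genes were lower in 9 of 17 (limma camera adjusted p = 0.0303, and adjusted p = 0.916 with an estimated correlation), Junb standing at -0.162 and Fos, an AP-1 subunit, at -0.150, or -0.0864 without control replicate 2. Heat shock and endoplasmic reticulum stress genes were higher in 15 of 19 (limma camera adjusted p = 0.0429, and adjusted p = 0.916 with an estimated correlation), with Xbp1, a transcription factor of the unfolded protein response, at 0.285, Pdia4, a disulfide isomerase, at 0.199 and Manf, a secreted stress-induced protein, at 0.167. Adjusted over the list alone, 0 members passed in each. Under the design as written 0 lists were called, at adjusted p values of 0.784 for the glucocorticoid list and 0.808 for the others. Glucocorticoid response was not called without control replicate 3 (0.355), and the activity-regulated list was not called without control replicate 2 (0.817), control replicate 3 (0.348) or yellow soybean replicate 2 (0.834), or with array medians aligned (0.114) or quantile normalization (0.0796). With the centred probe sets left out, the glucocorticoid list stood at 0.711, and activity-regulated (0.882) and heat shock genes (0.808) were in the opposite direction. Heat shock genes were not called without control replicate 1 (0.837, in the opposite direction), control replicate 2 (0.0986), yellow soybean replicate 1 (0.133), yellow soybean replicate 3 (0.371), green soybean replicate 1 (0.0612) or green soybean replicate 3 (0.0675). Nor were they called with a gene's probe sets averaged (0.290) or with a replicate block (0.0667). Among the 24 lists not called, the smallest camera adjusted p was 0.250, for microglia markers. The camera direction was lower despite a positive median and mean for both amyloid lists, antioxidant defence, oxidative phosphorylation and cholesterol synthesis, and median and mean differed in sign for the circadian, thalamus and habenula, and endothelium and pericyte lists.

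**Figure D4:**
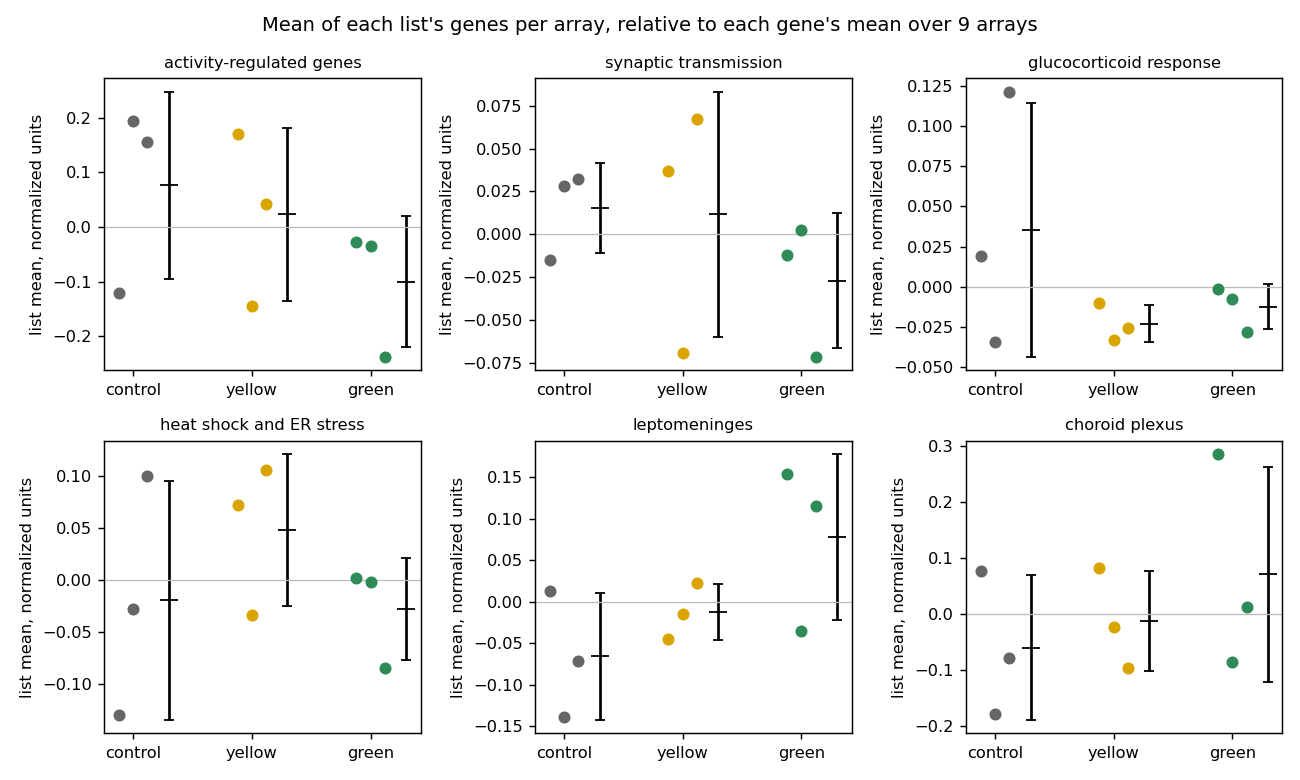
Points give the mean of a list's genes on each array, in normalized units relative to each gene's mean over the 9 arrays, for 6 lists by diet, with the group mean and SD drawn beside them. The diets overlap in activity-regulated genes, where control replicate 1 lies at -0.120, and control replicate 3 lies apart in glucocorticoid response at 0.121.

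The comparison of green with yellow soybean tests whether the effects of both extracts differ. Heat shock and endoplasmic reticulum stress genes were lower with green than with yellow soybean in 16 of 19 members (limma camera adjusted p = 2.73e-04, and adjusted p = 0.998 with an estimated correlation), with Hspb1, a small heat shock protein, at -0.209, Manf at -0.123 and Dnajb9, a co-chaperone of the endoplasmic reticulum, at -0.0954. Activity-regulated genes were lower in 15 of 17 (limma camera adjusted p = 4.27e-04, and adjusted p = 0.998 with an estimated correlation), with Nr4a1 at -0.348, Egr2 at -0.264 and Arc, a regulator of synaptic receptor trafficking, at -0.249. Without yellow soybean replicate 1 these were -0.213, -0.138 and -0.154, and without green soybean replicate 3 Nr4a1 stood at -0.218, Arc at -0.142 and Hspb1 at -0.129. Hspb1 stood at -0.330 without green soybean replicate 1. Adjusted over the list alone, 0 members passed in either list. Under the design as written, the heat shock list was called at 0.0481, and leptomeninges and oxidative phosphorylation were higher at the same value, all 3 at adjusted p = 0.959 with an estimated correlation, while activity-regulated genes were not called at 0.455. Activity-regulated genes were also not called without green soybean replicate 3 (0.0929) or yellow soybean replicate 1 (0.213), or with the centred probe sets left out (0.371).

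Ptgds was higher with green than with yellow soybean by 0.396, with yellow soybean replicate 3 at 0.679 above the green arrays (0.649 without it, and 0.254 without yellow soybean replicate 1). Aplp1 differed by -0.943, or -1.33 to -0.719 with single arrays left out. Its score in yellow soybean replicate 3, -0.653, was level with the highest green array. Higher genes with the smallest p values were Krtap5-2, a keratin-associated protein, at 0.357, Elf4, an ETS transcription factor, at 0.325, Mhrt at 0.308, Olfr1229, an olfactory receptor, at 0.279 and Spata21 at 0.267. Lower genes included U2af1, a splicing factor, at -0.424, Ssh2, a cofilin phosphatase, at -0.332, Mir381, a microRNA, at -0.318 and Dip2c at -0.282. None passed, with limma adjusted p = 0.687 for Ptgds and 0.634 for the others. In controls Krtap5-2, Elf4, Mhrt, Olfr1229, Spata21 and Ssh2 averaged between -0.597 and -1.87e-04, below the median of 0.128 over the probe sets tested. U2af1 and Dip2c lay above it, at 0.435 and 0.199. Limma called 0 probe sets, and 1 (Nfu1, 0.649, adjusted p = 0.0283) without green soybean replicate 3, with 1559 at an unadjusted p below 0.05, 1222 higher and 337 lower, against 1098 by chance, but 348 against 549 under the design as written. The higher share of 78.4% became 64.0% with array medians aligned and 47.5% after quantile normalization, and was 34.3% among the brightest probe sets without rescaling. The green arrays lay wholly above the yellow ones in 1675 probe sets and below in 642, together 10.6%, where chance gives 10%. Among the 25 lists not called, synaptic transmission and leptomeninges came nearest, both at 0.0537. The camera direction was lower despite a positive median and mean for amyloid beta binding and clearance, glucocorticoid response, thalamus and habenula, neocortex, astrocyte and microglia lists, and amyloid precursor processing had a positive median with a negative mean.

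The moderated F-test of any difference between the 3 diets called 0 probe sets in limma, the smallest adjusted p being 0.683, with 1550 at an unadjusted p below 0.05 (1098 by chance, and 337 against 549 under the design as written), and 1, Nfu1, was called without green soybean replicate 3. The differences of both extracts from the shared controls correlated across probe sets with r = 0.423, where simulated unchanged groups against the same controls gave 0.501 ± 0.0110 (SD over 100 draws). The covariance was 0.00246 against a simulated 0.00309, and 64.9% of probe sets had the same sign against 66.6%. Probe sets are not independent replicates, and the observed values did not exceed those that the shared controls alone produce.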

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

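The tests of neighbouring tissue in green soybean replicate 3, of the choroid plexus, the leptomeninges and single arrays for Ptgds, of shared variation and centring for the activity-regulated genes, and all settings of the centred probe sets were chosen after the results were seen. For the neighbouring tissue, the choroid plexus and the centring, the reading of the test was also settled after its value was seen, and the count under the design as written was added then.

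Single arrays lay far from the other 8 in 6 of 36 measures, where about 1.8 would arise by chance at 1 in 20. The highest score of green soybean replicate 1 was 3.02, below those of the others, which began at 3.27, and the median of 10 control-type probe sets was 0.901 on it, against 1.78 to 2.12. Those 10 were picked by a deposited p-value below 0.005, so they are not a neutral quality measure, and over 3676 control-type probe sets the array's median, 0.190, lay within the range of the others. Green soybean replicate 3 had the lowest mean correlation, 0.958, the widest spread of differences, 0.160, and the lowest mean of cornu ammonis pyramidal cell markers, -0.127. Control replicate 3 had the highest mean of glucocorticoid response genes, 0.121. Between the extracts, activity-regulated genes (limma camera adjusted p = 4.27e-04) and heat shock genes (limma camera adjusted p = 2.73e-04) differed, and both calls ended with an estimated correlation at 0.998. The unadjusted camera p values there were 0.235 and 0.181, and the loss of a call in that setting does not show that the lists are equal. In the authors' deposited table, which the comparisons do not use, 914 of 21605 p-values passed a Benjamini-Hochberg adjusted p of 0.05, for a comparison that is not stated. Whether those p-values measure the spread between arrays is not known either. For Aplp1 the deposited p-value was 1.06e-14, against an unadjusted p of 0.0244 in the moderated F-test, which called 0 probe sets. The 914 are therefore not read as differences between diets.

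Green soybean replicate 3 separated from the other arrays along the first principal component, which held 30.4% of the variance. Tissue of a neighbouring structure would raise the markers of that structure in it, and 0 of the 6 marker lists of neighbouring structures were highest in this array. Under the design as written, however, 1 of 5 was, the 4 leptomeninges markers left by its filter averaging 0.266 against at most 0.152 elsewhere, so this explanation stays open. A distortion of the scale that follows signal level would vanish once the trend is removed, but its mean correlation was then 0.965, still below the lowest other array at 0.977. RNA quality, handling and a difference between mice were not tested and remain open, and no diet group is this array alone.

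Ptgds was higher in the green arrays than in the controls. Without green soybean replicate 3 the lowest green array still exceeded the highest control by 0.284. All 3 green arrays lay above the controls, so leaving that array out could not create an overlap, and this gap decides nothing. With single arrays left out, the difference ranged from 0.519 to 0.653, so its size did not rest on 1 array. Leptomeninges carried along in the dissection may account for it: over the 9 arrays Ptgds correlated with the leptomeninges markers at r = 0.749 (exact permutation p = 0.0176, adjusted over 2 relations 0.0352; rho = 0.733, exact p = 0.0311, adjusted 0.0622), but r was 0.481 without green soybean replicates 1 and 3 and 0.497 within diets, so part of the relation rests on those arrays. For the choroid plexus r was 0.255 (exact permutation p = 0.538; rho = -0.0333, exact p = 0.948) and -0.544 without the 2 farthest arrays, which is too few arrays to decide. An effect of the green extract on Ptgds also stays open, untested apart from the dissection.

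Activity-regulated genes were lower with green soybean at the preset correlation. The call stands without green soybean replicate 3 (limma camera adjusted p = 2.08e-05), so that array alone does not make it. Variation between arrays that these genes share is a candidate explanation, because with an estimated correlation the adjusted p was 0.793 and control replicate 1 lay below 2 of the green arrays. Without the centred probe sets the adjusted p was 0.391, but those 9 of 17 members, with a median difference of -0.317 against -0.0331 for the other 8, were selected by the authors' p-value, so leaving them out cannot be told apart from leaving out the members that differ most. An effect of the diet stays open, and handling before death, which also moves these genes, was not tested.

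Other splits of the 6 arrays of each comparison number 10 with the real one, too few for a share below 0.05. A real count of 0 is reached by any split, so those comparisons decide nothing. For green versus control, the real split called 0 probe sets and another called 1 (10 of 10 as large), 2134 probe sets passed unadjusted against at most 1444 in the others (1 of 10), and 4 lists were called against up to 9 (6 of 10). For yellow versus control the real and highest other values were 0 and 0 (10 of 10), 667 and 1297 (8 of 10) and 3 and 10 lists (9 of 10). For green versus yellow they were 0 and 1 (10 of 10), 1559 and 1612 (2 of 10) and 2 and 8 lists (8 of 10). For the F-test, 100 drawn splits of the 9 arrays gave up to 8 calls against 0 (100 of 100, fixed by the real count of 0). At an unadjusted p below 0.05 they gave up to 1724 against 1550 (6 of 100), so for that count chance cannot be excluded.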

How the results depend on the processing

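The reported setting, the array weights, the array medians, quantile normalization for the gene lists, the restriction to 1 symbol and the handling of the centred probe sets were chosen after results had been seen. Counts of called probe sets were 0 in every comparison and setting except that Nfu1 alone was called without green soybean replicate 3 (1 for green versus control, 1 for green versus yellow, 1 in the F-test) and with array weights (1 for green versus control), so single arrays left out gave 0 to 1, and yellow versus control 0 to 0. Under the design as written, 557, 174, 348 and 337 probe sets passed unadjusted for green versus control, yellow versus control, green versus yellow and the F-test. These are 5.07%, 1.58%, 3.17% and 3.07% of 10980, against 9.72%, 3.04%, 7.10% and 7.06% of 21959, so the share fell as well as the number tested. Only the 5490 brightest probe sets gave 155, 35, 102 and 69, and the dimmer probe sets left out gave 855, 211, 510 and 535 of 11652. For yellow versus control, array weights gave 1091 and leaving out yellow soybean replicate 2 gave 1059. Gene list calls, in the order green versus control, yellow versus control and green versus yellow, were 4, 3 and 2. They were 0, 0 and 0 with an estimated correlation and with fry, whose smallest adjusted p were 0.371, 0.982 and 0.949. They were 7, 2 and 2 with a gene's probe sets averaged, 1, 0 and 3 under the design as written, 1, 0 and 1 with the centred probe sets left out, and 3, 5 and 3 with only the dimmer uncentred ones left out. Leaving out single arrays gave 2 to 8 (2 without green soybean replicate 1, 8 without control replicate 1), 1 to 6 (1 without control replicates 2 or 3, 6 without control replicate 1) and 1 to 7 (1 without green soybean replicate 3, 7 without green soybean replicate 2). Directions were reversed for yellow versus control with the centred probe sets left out, for activity-regulated (0.882) and heat shock genes (0.808), for heat shock genes without control replicate 1 (0.837, the range over single arrays being 5.89e-07 to 0.837), and for Ptgds without yellow soybean replicate 3 (-0.0797, the range being -0.0797 to 0.315). The cause was not tested. Nothing states that the replicate numbers pair the arrays: 2 of 9 same-numbered pairs correlated above 0.1, 3 of 9 arrays had their best partner under their own number, where chance gives 3, and 0 of 9 correlated best with their own number in both other diets. A replicate block gave 0 called probe sets, 5, 2 and 6 gene lists (the yellow heat shock call ended at 0.0667), and left the correlation of both effects at 0.423. That correlation ranged from 0.327 to 0.526 over single arrays left out. Across 1150 values of 62 named gene results, 1 was reversed and 2 passed the threshold. The intensity trend was in the design, and its use became an alternative when the reported setting was chosen. Rescaling each array by its own deposited parameters was not run, because their columns match no label, nor was the authors' p-value as a test, because its comparison is not stated.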

Other observations

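The tests in this part were chosen after the results were seen. In the authors' deposited table, probe sets with a p-value below 0.005 were concentrated in a few gene lists. They made up 9 of 17 probe sets of activity-regulated genes (Fisher's exact test, adjusted p = 3.92e-06 over 27 lists) and 9 of 19 of synaptic transmission genes (6.68e-06), against a background share of 6.02% among single-symbol probe sets. The synaptic ones included the glutamate receptor subunits Gria1, Gria2, Grin2a and Grin2b, the kinases Camk2a and Camk2b and the postsynaptic scaffolds Dlg4 and Shank1. Leptomeninges markers had 7 of 16 (1.68e-04), among them the fibrillar collagens Col1a1, Col1a2 and Col3a1, and heat shock and endoplasmic reticulum stress genes 7 of 27 (0.00549). Glucocorticoid response genes and GABAergic interneuron markers, the latter with Lhx6, Npy, Reln and Sst, each had 4 of 13 (0.0262). The comparison behind those p-values is not stated, they carry no direction, and genes of a list are not independent in this test. It is also not known whether those p-values measure the spread between arrays, so the concentration does not show a difference between diets.

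Of the 1345 probe sets with such a p-value, 36.1% had no overlap between the green and control arrays, 14.2% between yellow and control and 20.3% between green and yellow. Among the other tested probe sets the shares were 14.5%, 8.98% and 9.92%. The 1345 were selected by a p-value of the same table, so shares above those of the other probe sets follow from the selection, and the 10% of chance is no reference for them. The F-test in limma called 0 of the 1345, with 272 at an unadjusted p below 0.05.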
